A study of Mus musculus with 53 samples.

How the data were processed

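RNA was measured in 53 mouse tumour libraries of 18 groups in 3 experiments. Per the labels' protocols, cells were injected in Matrigel into the inguinal mammary fat pads of female mice, RNA was extracted with Qiagen RNeasy, and stranded TruSeq mRNA libraries were made from 500 ng of RNA. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.1b and normalized with edgeR. The gene annotation and the tool that counted reads are not given in the sources used here.

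Each experiment has its own table of deposited log2 values for each gene and library, which the authors scaled by trimmed mean of M values (TMM) factors over the libraries of that experiment. The deposited values were checked against whole read counts. Read as log2(CPM + 1), with a pseudocount of 1, they gave whole counts within 0.1 of a read for 100% of the values tested in every library, and this also gave the depth of each library. Assigned reads, with M for mega, ran from 3.23 to 7.75 M in the YM-155 experiment, 9.57 to 15.5 M in the antibody experiment and 5.25 to 12.2 M in the time course, and TMM factors from 0.863 to 1.10. A single read is worth 0.134 to 0.358 CPM in the first, 0.0623 to 0.107 in the second and 0.0828 to 0.185 in the third, so a level of 1 CPM rests on few reads in the YM-155 experiment. On this scale a difference between groups is smaller than the log2 ratio of their CPM when the gene is low.

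Tables held 24360, 20185 and 19176 genes in the order YM-155, antibody, time course. Symbols were deposited in capitals and were matched to GENCODE M21 symbols (96.3%, 98.5% and 96.6%), then to RefSeq symbols and synonyms. Symbols turned into dates by a spreadsheet, 27, 25 and 27 of them, were left out because they could not be assigned to a gene; they held at most 0.223% of the reads of a library. All columns were matched to a sample. Coordinates are those of GENCODE M21 on mm10.

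Groups were taken from the sample titles. In the YM-155 experiment the genotype field follows the treatment and disagrees with the title in 12 libraries. The host is given as NSG in titles, and its strain field names a scid and Il2rg mutant that also carries human cytokine transgenes. The WGD- anti-CD8 group has 2 libraries and the others 3.

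Before the data were examined, the groups, contrasts, tests, gene lists, naming rule and main alternatives were written down. Each table was fitted on its own in R 4.3.3 with limma 3.58.1, with a mean per group, the mean-variance trend and robust empirical Bayes. Genes above 1 CPM in at least 3 libraries were tested: 13826, 13840 and 13478. The plan gave this filter as log2 CPM above 0 with 1 CPM beside it, and because the deposited scale adds 1 before the log, it was applied at 1 CPM. There were 23 contrasts, 6 of them differences between effects, fitted as interactions. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. The 33 lists, of 379 genes in all, were tested with camera at its preset correlation of 0.01 where at least 3 members were tested, with adjustment over the lists of a contrast. Beside each call stand camera with an estimated correlation and the count of members past 0.05 with adjustment over all genes and over the list alone.

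The text names genes by a rule: the targets of the manipulations; up to 6 genes each way with the largest change among those called whose groups do not overlap and whose higher group averages at least 3, leaving out gene models without their own symbol and receptor segments; and in each list called by camera up to 4 called members, or up to 2 with the smallest p where none was called. Differences between effects name up to 4 genes each way. Genes named outside the rule are marked as such.

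Alternatives set beforehand were no filter, log2(2^value + 1), quantile normalization, a model of only the groups compared, the replicate number as a block, leaving out each library in turn, and for the lists an estimated correlation and fry. Added after the data were seen were a filter on deposited values above 0 in 3 libraries, voom on the recovered reads, and leaving out libraries that stand apart or also those that score as the other genotype. A library stands apart when its best correlation with another library of its table lies more than 3 median absolute deviations under the median. The main model holds no block, because the labels do not say that a replicate number marks a shared litter, batch or day. The numbers were also tested as pairs, and in 0 of 17 contrasts did all pairs correlate above 0.1. This does not exclude pairing. For WGD at day 14 the pairs lay between 0.0920 and 0.159, and 6 of 6 libraries correlated best with their own number. For hosts in WGD- vehicle tumours 5 of 6 did. No 2 libraries of a table were identical. Each split of 3 against 3 libraries was counted, and 100 regroupings were drawn for differences between effects with seed 20.

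The fit was tested on simulated data of the same size in 4 contrasts, with 100 genes changed by a log2 of 1 and 100 by 2. In NSG vehicle tumours 64 and 92 were found, in the difference between hosts 29 and 76, under isotype antibody 56 and 81, and at day 14 34 and 76. Of the unchanged genes 5, 5, 10 and 8 were called. Each simulated gene was drawn independently around a mean shared by all groups. The simulation held no correlated genes, no groups of unequal spread and no libraries that stand apart. Its false calls therefore do not show how many the real data would give. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 and in R with data.table version 1.17.8, and figures were drawn with matplotlib 3.10.9. The sequence reads were not analysed here, and the tables were not merged because each was normalized on its own.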

Results

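Bulk RNA sequencing was carried out on 53 libraries from mouse tumours grown from TA3 Hauschka cells, a mammary tumour line of the mouse. The line was engineered into a form without whole genome doubling (WGD-) and a form with it (WGD+). Cells of either form were placed in the mammary fat pad of 6-week-old female mice. The hosts were A/J mice, which have an intact immune system, or an immunodeficient strain labelled NSG, whose mutations in Prkdc and Il2rg leave it without mature T, B and NK cells. The libraries fall into 18 groups in 3 experiments. In the first, tumours in both hosts received vehicle or YM-155, a small molecule described as a suppressor of survivin (gene Birc5), for 14 days, with 8 groups of 3 libraries. In the second, A/J tumours received an isotype control antibody, anti-PD-L1 or anti-CD8 for 14 days, with 5 groups of 3 libraries and 2 libraries of WGD- tumours under anti-CD8. In the third, A/J tumours were collected at day 8 or day 14, with 4 groups of 3 libraries.

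Libraries held 3.23 to 7.75 M assigned reads in the YM-155 experiment (median 6.73 M), 9.57 to 15.5 M in the antibody experiment (median 12 M) and 5.25 to 12.2 M in the time course (median 9.93 M). Levels are given as log2(CPM + 1) with the SD over the libraries of a group, and changes as differences of these levels with the standard error (SE) of the limma fit. Differences on this scale understate the change of low genes. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries only. The fit takes that spread over all groups of an experiment, not over the compared libraries alone. A group that varies more or less than the others is thus judged by the shared spread. Where a list of genes is called, the call is that of camera at its preset correlation, and none of the 263 calls over all comparisons held with an estimated correlation. Genotype was taken from the sample titles, because in the YM-155 experiment the genotype field disagreed with the title in 12 libraries. A genotype score, set by the 43 genes at least 2-fold higher and the 123 genes at least 2-fold lower in NSG WGD+ vehicle tumours, lay between -1.70 and -0.725 in the 12 libraries titled WGD- and between 0.275 and 1.60 in the 12 titled WGD+. The 6 NSG vehicle libraries among them set the score and so are no test of it.

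The first comparison asked how WGD+ tumours differ from WGD- tumours in NSG mice, where mature lymphocytes are lacking. Slc7a11, which encodes the cystine and glutamate exchanger (chromosome 3, 49892526 to 50443614 in mm10, minus strand), was at 6.87 ± 0.30 in WGD+ and 4.28 ± 0.14 in WGD- tumours (SD, n = 3 each), a rise of 2.59 (SE 0.27, limma adjusted p = 7.09e-06). Mfge8, a secreted glycoprotein that binds phosphatidylserine (chromosome 7, 79133768 to 79149060), rose by 1.99 (SE 0.17, adjusted p = 4.43e-07). The retinol uptake receptor gene Stra6, the cyclin gene Ccnd2 and the keratin gene Krt23 rose by 2.17, 1.98 and 1.73. Lpar3, a receptor for lysophosphatidic acid (chromosome 3, 146220963 to 146286186), was at 0.83 ± 0.08 against 4.39 ± 0.23 and fell by 3.56 (SE 0.37, adjusted p = 7.09e-06). Crabp2, which carries retinoic acid inside cells, fell by 3.33 (SE 0.39, adjusted p = 4.28e-05), and the laminin receptor gene Itga7 fell by 3.13 (SE 0.41, adjusted p = 0.00026). The matrix gene Matn4, the protease gene Pappa and the transcription factor gene Sp6 fell by 3.08, 3.08 and 3.07.

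Among the fixed lists, keratin and epithelial genes were lower in NSG WGD+ tumours (camera adjusted p = 0.00393, adjusted p = 0.875 with an estimated correlation). Of its 11 members, Krt7 fell over all genes tested (-1.29, limma adjusted p = 0.013) and 3 fell when adjusted over the list alone. Skeletal muscle genes had a median change of -1.35 (adjusted p = 0.931 with an estimated correlation), with 0 of 10 past the threshold over all genes and 8 adjusted over the list alone. The library of WGD- replicate 2 held Acta1, the actin of skeletal muscle, at 10.3. The type I interferon list was called higher with a median of 0.68, and 0 of its 20 members passed either adjustment (adjusted p = 0.931 with an estimated correlation). In all, 394 of 13826 genes changed (limma adjusted p under 0.05), 124 higher and 270 lower. The count was 2462 with only the 6 libraries compared in the model and 256 with no filter. Leaving out WGD- replicate 1, 2 or 3 gave 132, 194 or 123 genes, and leaving out WGD+ replicate 1, 2 or 3 gave 169, 107 or 156. Of the 13 genes named by rule and past the threshold, 8 stayed past it with each library left out in turn, among them Slc7a11, Mfge8, Lpar3, Crabp2 and Itga7.

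**Figure D1:**
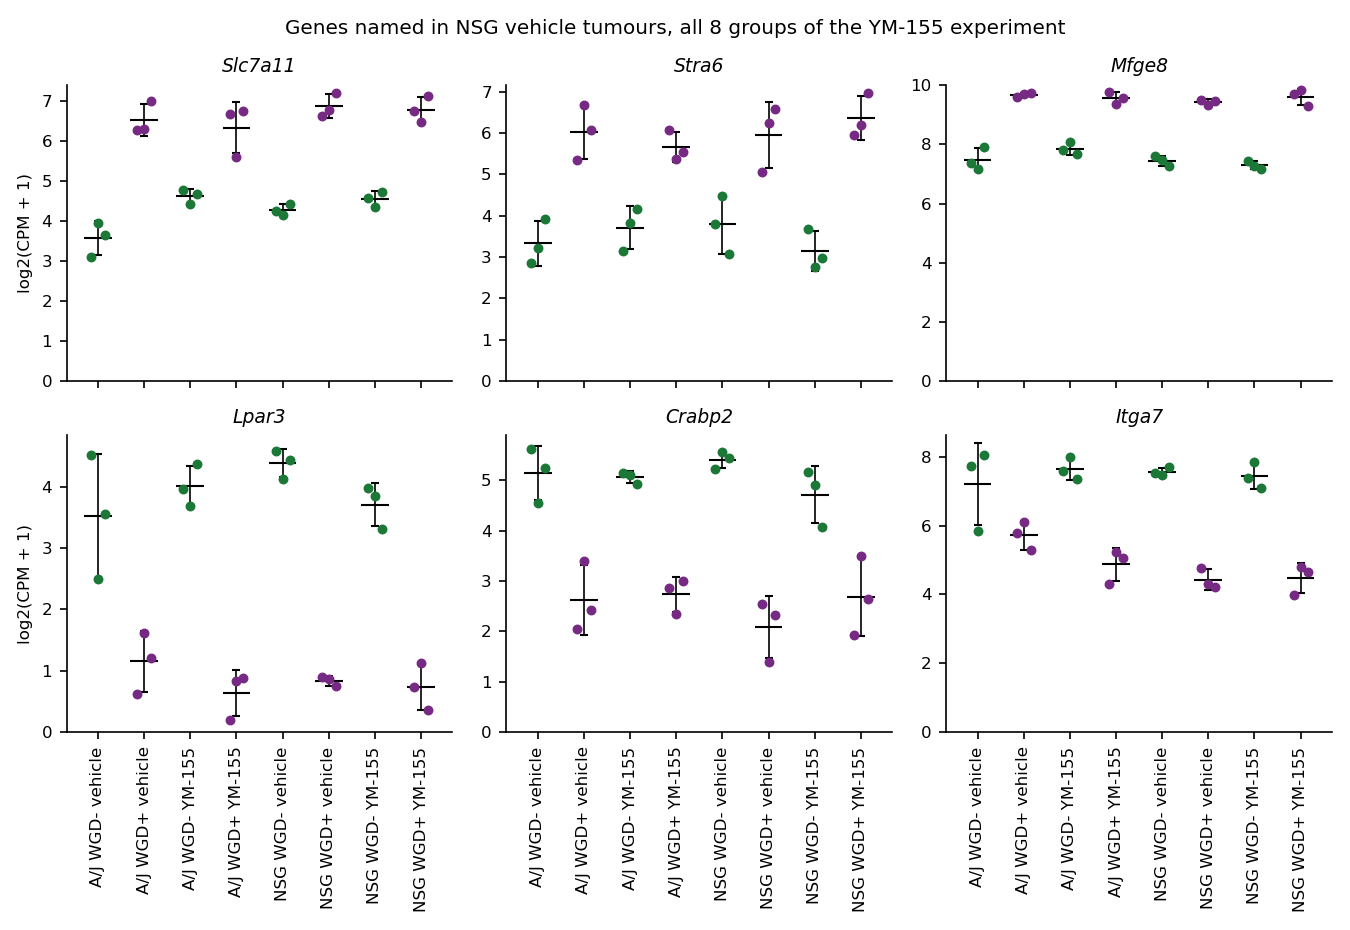
Level of 6 genes, as log2(CPM + 1), in each library of the 8 groups of the YM-155 experiment, with group mean and SD as black lines and WGD- libraries in green and WGD+ in purple. Slc7a11 averaged 6.87 in NSG WGD+ and 4.28 in NSG WGD- vehicle tumours, and Lpar3 averaged 0.83 and 4.39.

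In A/J vehicle tumours the same comparison was made in mice with an intact immune system. Slc7a11 was at 6.52 ± 0.41 in WGD+ and 3.57 ± 0.42 in WGD- tumours (SD, n = 3 each), a rise of 2.95 (SE 0.27, limma adjusted p = 6.08e-07), and Stra6, Mfge8 and the phosphodiesterase gene Pde2a rose by 2.71, 2.19 and 1.86. Cell cycle genes were higher: of 15 members of the G2/M list, 7 rose over all genes and 10 adjusted over the list alone, among them the kinesin gene Kif11 (1.03), the proliferation marker Mki67 (0.93), the mitotic kinase gene Aurkb (0.91) and the topoisomerase gene Top2a (0.82). That list was called higher (camera adjusted p = 1.81e-06, adjusted p = 0.634 with an estimated correlation). The replication helicase genes Mcm3, Mcm6 and Mcm2 each rose by 0.78, and the spindle checkpoint gene Zwilch rose by 0.82. Markers of cytotoxic lymphocytes were lower: Nkg7 fell by 1.96 (SE 0.30, adjusted p = 0.00056), Cd8a by 1.55 and the granzyme gene Gzma by 1.10, and of the list's 8 tested members 3 fell over all genes and 6 adjusted over the list alone (adjusted p = 0.634 with an estimated correlation).

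Interferon-gamma response genes had a median change of -1.72 in A/J WGD+ vehicle tumours, and 3 of 17 fell under both adjustments (camera adjusted p = 1.81e-06, adjusted p = 0.634 with an estimated correlation). These were the nitric oxide synthase gene Nos2 (-2.45), the tryptophan-degrading enzyme gene Ido1 (-1.60) and the cytokine signalling inhibitor gene Socs1 (-1.32), whose calls held in 3, 6 and 0 of 6 leave-outs. The 12 genes of MHC class I presentation had a median of -1.05 with 0 past either adjustment (adjusted p = 0.634 with an estimated correlation). The genes with the largest falls included liver secretory transcripts, with albumin (Alb) at 0.98 ± 1.09 against 6.51 ± 3.31 (-5.53, SE 1.33, limma adjusted p = 0.0155) and Apoa1, Ttr, Cyp2e1 and Mup3 at -3.85, -3.40, -3.26 and -2.91. Alb was at 10.04 in WGD- replicate 2, 6.01 in replicate 3 and 3.48 in replicate 1. Il1rl1, the receptor for interleukin 33, fell by 3.46 (SE 0.61, adjusted p = 0.00233). In all, 1534 of 13826 genes changed, 871 higher and 663 lower. With only the 6 libraries compared in the model 44 genes passed, with no filter 908 and by voom 917. The count was 583 without WGD- replicate 2, 2444 without WGD- replicate 3, 634 without WGD+ replicate 1 and 445 without WGD+ replicate 3, and it was 95 without WGD- replicates 1 and 2, which correlated least with the other libraries. That last count sets 1 WGD- library against 3, with its spread taken from the other groups. Of the 29 named genes past the threshold, 14 stayed past it with each library left out, among them Slc7a11, Mfge8, Cd8a, Ido1, Kif11 and Mki67, and Alb kept its call in 3 of 6.

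The difference of the WGD effect between hosts was tested as an interaction. Of the 394 genes called in NSG tumours, 367 had the same direction in A/J vehicle tumours, and 159 were called there too. Of the 1534 genes called in A/J vehicle tumours, 1245 had the same direction in NSG tumours. The interferon-gamma list had a more negative WGD effect in A/J than in NSG tumours, with a median difference of -1.90 (camera adjusted p = 4.48e-09, adjusted p = 0.488 with an estimated correlation), 0 of 17 genes past the threshold over all genes and 1 adjusted over the list alone. Its mean level was 6.31 in WGD- and 4.55 in WGD+ tumours of A/J mice and 2.45 and 2.87 in those of NSG mice. In the other direction the skeletal muscle list differed by a median of 2.10, with 0 of 10 genes past the threshold over all genes and 9 adjusted over the list alone, and the G2/M list by 0.58, with 0 of 15 and 4 (adjusted p = 0.488 with an estimated correlation for both). Within the YM-155 experiment the muscle list reaches 7.62 in the NSG WGD- vehicle group. Single genes did not pass: limma called 0 of 13826, with 1787 at an unadjusted p under 0.05, and voom called 0. Without A/J WGD- vehicle replicate 3, 135 genes passed, and 2 did with only the libraries compared in the model.

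The hosts were compared within each form of the tumour. They differ in strain as well as in immune system, and the strain field of the NSG host also names human cytokine transgenes. What part these play in the differences between hosts was not tested. In WGD- vehicle tumours, genes induced by interferon-gamma were far higher in A/J than in NSG mice. The guanylate-binding protein genes Gbp2b and Gbp4 rose by 6.60 and 6.47, the GTPase gene Iigp1 by 5.99, and Cxcl9, a chemokine that draws T cells (chromosome 5, 92321347 to 92328079), by 5.85 (SE 1.14, limma adjusted p = 0.00115) to 6.31 ± 0.63 from 0.45 ± 0.15 (SD, n = 3 each). Of the list, 16 of 17 rose over all genes and 17 adjusted over the list alone. All 12 MHC class I presentation genes rose under both adjustments, with the immunoproteasome gene Psmb9 at 5.10, the peptide transporter gene Tap1 at 4.14 and H2-K1 (chromosome 17, 33996017 to 34000347) at 4.13. Of 20 type I interferon genes 18 rose over all genes and 20 adjusted over the list alone, and of 8 cytotoxic lymphocyte genes 7 rose under both, led by the granzyme gene Gzmb (2.71). In the other direction, 12 of 15 G2/M genes fell under both adjustments (Kif11 -1.40, Aurkb -1.39, Ccnb1 -1.28), as did 4 of 11 fibroblast and matrix genes (Col6a3 -2.08). The adjusted p with an estimated correlation was 0.361 for the interferon-gamma, MHC class I, type I interferon, cytotoxic and G2/M lists and 0.54 for the fibroblast list. Alb, listed at 0 in the 3 NSG WGD- vehicle libraries, was at 6.51 ± 3.31 in A/J WGD- tumours. The skeletal muscle genes Myh1 and Mylpf were also called between hosts, and each call held in 2 of 6 leave-outs. NSG WGD- vehicle replicate 2 held Acta1 at 10.3.

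Of the genes mutated in the NSG strain, Il2rg, the common cytokine receptor chain (X chromosome, 101264378 to 101268255), was higher in A/J WGD- tumours by 1.79 (SE 0.33, limma adjusted p = 0.000544). Prkdc, the DNA repair kinase gene (chromosome 16, 15637866 to 15842235), differed by -0.63 and did not pass (adjusted p = 0.073). In all, 4768 of 13826 genes changed between hosts in WGD- tumours, 2244 higher and 2524 lower in A/J. The count was 2976 with only the 6 libraries compared in the model, and 2310 without A/J WGD- replicates 1 and 2, which stand apart and leave 1 A/J library. Of the 60 named genes past the threshold, 49 stayed past it with each library left out. The cytosolic ribosome list was called higher in A/J (adjusted p = 0.54 with an estimated correlation), with 6 of 13 members past both adjustments, though Rpl3 (0.49) turned to -0.0051 under quantile scaling.

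In WGD+ vehicle tumours MHC class I genes were again higher in A/J mice. Of 12 MHC class I genes 10 rose in A/J over all genes and 12 adjusted over the list alone, with a median of 2.29 against 3.67 in WGD- tumours. Psmb9, Psmb8 and H2-K1 rose by 2.92, 2.56 and 2.56 (adjusted p = 0.477 with an estimated correlation for the list). Of 17 interferon-gamma genes 2 rose over all genes, Irf1 (1.87, call kept in 1 of 6 leave-outs) and Socs1 (1.34, in 0 of 6), and 4 adjusted over the list alone (adjusted p = 0.624 with an estimated correlation). Fibroblast and matrix genes fell, 5 of 11 over all genes and 8 adjusted over the list alone, with the collagen gene Col3a1 at 4.39 ± 0.29 against 7.96 ± 0.03 (-3.57, SE 1.10, limma adjusted p = 0.042) and Lum at -2.52 (adjusted p = 0.504 with an estimated correlation). The call of Col3a1 held in 0 of 6 leave-outs and that of Lum in 6. The adipokine gene Adipoq fell by 2.24, and all 4 mast cell genes tested fell under both adjustments, led by the protease gene Mcpt4 (-1.53) (adjusted p = 0.477 with an estimated correlation). The calls of Mcpt4, Tpsb2, Cpa3 and Cma1 held in 5, 1, 0 and 0 of 6 leave-outs. The keratin gene Krt42 rose by 3.53 and the apoptosis effector gene Bax by 1.33. Il2rg was higher by 1.44 (adjusted p = 0.00963). In all, 1731 genes changed, 996 higher and 735 lower. With only the 6 libraries compared in the model 4139 passed, and with no filter 929. The count was 478 or 816 without A/J WGD+ replicate 2 or 3, and 835, 597 or 417 without NSG WGD+ replicate 1, 2 or 3. Of the 44 named genes past the threshold, 7 stayed past it with each library left out, among them Bax, Cox4i1, Krt42, Lum, Oas1a and Phlda3.

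YM-155 was compared with vehicle in each host and form, against the same vehicle libraries as in the comparisons of form and host. Birc5, the gene of survivin (chromosome 11, 117849251 to 117855743), did not pass in any of the 4 arms. Its change was -0.02 (SE 0.18) in A/J WGD-, 0.07 in A/J WGD+, 0.07 in NSG WGD- and 0.32 in NSG WGD+ tumours, and its group means lay between 6.78 and 7.17. In A/J WGD- tumours some inflammatory and interferon genes were called lower under YM-155. Of the 31 named calls in this arm, 0 held with each library left out in turn. Of 17 interferon-gamma genes 3 fell over all genes (Nos2 -2.29, Socs1 -1.86, Ido1 -1.51) and 17 adjusted over the list alone, with a median of -2.27 (camera adjusted p = 6.38e-12, adjusted p = 0.263 with an estimated correlation). The list's mean level ranged from 2.66 to 6.03 over the 3 YM-155 libraries. The chemokine gene Ccl2, the prostaglandin synthase gene Ptgs2 and Il1b fell by 2.15, 1.80 and 2.16, and the interleukin 1 antagonist gene Il1rn by 2.41. The macrophage list was lower with a median of -0.89, and 1 of its 13 members, Msr1 (-1.49), fell under both adjustments (adjusted p = 0.263 with an estimated correlation). Mitotic genes were higher, with Aurkb (1.05), Kif11 (0.91) and Kif20a (0.76) among 3 of 15 G2/M genes that rose over all genes and 12 adjusted over the list alone (adjusted p = 0.263 with an estimated correlation). The homeobox gene Dlx1, the oxidoreductase gene Nqo1 and the collagen gene Col4a2 rose by 1.61, 1.18 and 1.19, and Il1rl1 fell by 3.20 from 3.95 ± 2.10 to 0.75 ± 0.42 (SE 0.61, limma adjusted p = 0.0192).

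In all, 579 of 13826 genes changed in this arm, 307 higher and 272 lower. None of the 31 named calls held with each library left out: the count was 0 without vehicle replicate 2 or YM-155 replicate 3, 367 without YM-155 replicate 1 and 1815 without vehicle replicate 3. It was 0 without vehicle replicates 1 and 2, which leaves 1 vehicle library with its spread taken from the other groups, and where Lum and Dcn, at -1.41 and -2.22 with all libraries, stood at 0.38 and 0.96, and 1 when the model held only the 6 libraries compared. With no filter it was 69 and by voom 27.

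In A/J WGD+ tumours limma called 0 genes under YM-155, with 445 at an unadjusted p under 0.05 and 0 by voom. Without YM-155 replicate 2 it called 12. The interferon-gamma list had a median of -1.44 with 0 of 17 genes past either adjustment (camera adjusted p = 6.6e-11, adjusted p = 0.525 with an estimated correlation), and Cd274, the gene of PD-L1, differed by -1.45 without passing. In NSG WGD- tumours limma also called 0 genes, with 697 at an unadjusted p under 0.05 and 0 by voom. There the skeletal muscle, fibroblast and endothelial lists had medians of -1.25, -1.08 and -0.70, with 5 of 10, 1 of 11 and 2 of 10 members past the threshold when adjusted over the list alone and 0 over all genes (adjusted p = 0.159, 0.189 and 0.159 with an estimated correlation). Acta1 was at 10.3 in vehicle replicate 2. With only the 6 libraries compared in the model 5 genes passed. In NSG WGD+ tumours 1 gene passed, Timm17b, a subunit of the mitochondrial import channel (X chromosome, 7899357 to 7908351), which rose by 0.89 (SE 0.15, limma adjusted p = 0.0397). That call was lost on leaving out any library except YM-155 replicate 3, without which 14 genes passed, and also with no filter, with only the 6 libraries compared in the model and by voom. The YM-155 effect was not shown to differ between WGD+ and WGD- tumours: the interaction had 0 genes in A/J (1650 at an unadjusted p under 0.05, voom 0) and 0 in NSG tumours (1400, voom 0). In A/J it had 199 genes without WGD- vehicle replicate 3 and 1 without WGD+ YM-155 replicate 3, and in NSG tumours 2 without WGD+ YM-155 replicate 1 and 29 with only the libraries compared in the model.

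**Figure D2:**
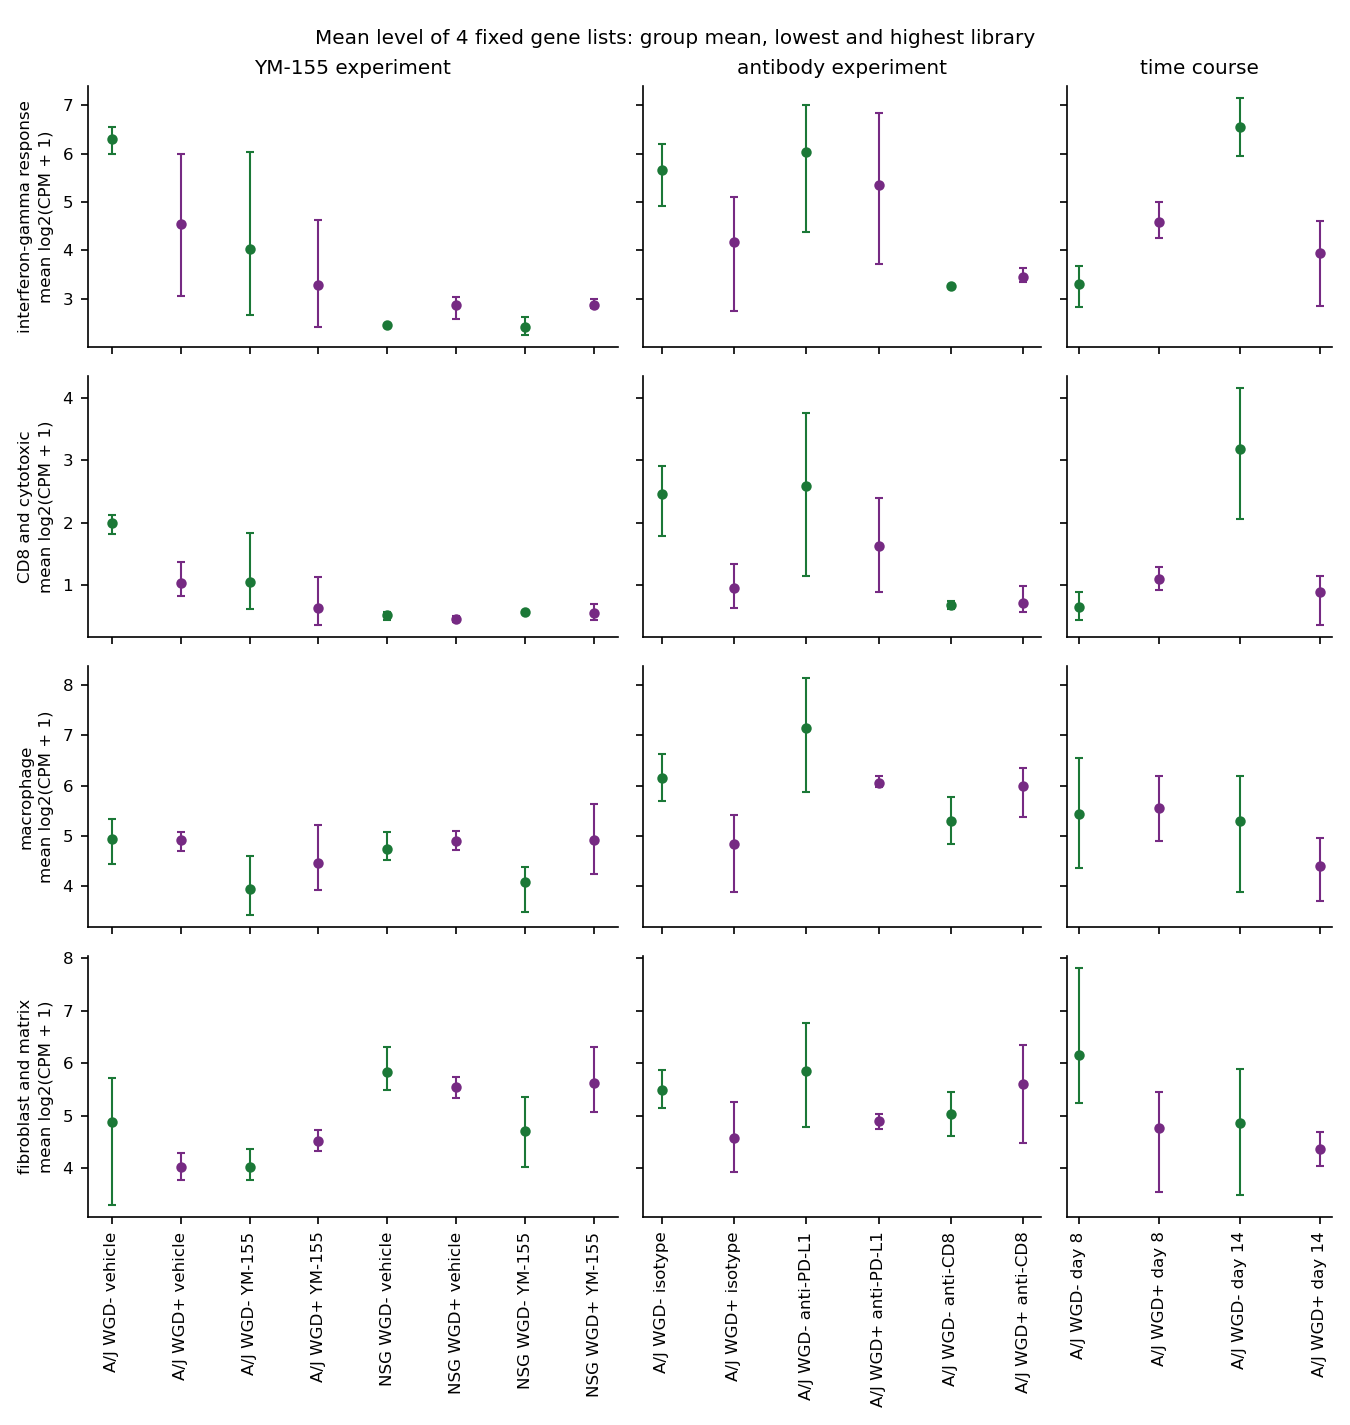
Mean level of 4 gene lists, as log2(CPM + 1), in the groups of the 3 experiments, with the group mean as a point and the lowest and highest library as a bar, WGD- in green and WGD+ in purple. The interferon-gamma list averaged 6.31 in A/J WGD- vehicle and 2.45 in NSG WGD- vehicle tumours, and 6.55 in A/J WGD- and 3.94 in A/J WGD+ tumours at day 14.

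In the antibody experiment the form of the tumour was compared under isotype antibody. Granzymes of the cluster on chromosome 14 were lower in WGD+ tumours: Gzmg (56156582 to 56159579) was at 1.04 ± 1.33 against 4.78 ± 1.74 (SD, n = 3 each), a fall of 3.74 (SE 0.78, limma adjusted p = 0.038), and its neighbours Gzmf, Gzmd and Gzmc fell by 3.61, 3.56 and 3.05. These genes are close paralogs, and how reads shared between them were counted is not given in the sources used here. Nos2 (chromosome 11, 78920787 to 78960254) fell by 2.99 and Acod1, which makes itaconate in activated macrophages, by 2.90. Of 14 NF-kB and cytokine genes 2 fell over all genes, Ptgs2 (-2.07, adjusted p = 0.002) and the chemokine gene Cxcl2 (-1.95), and 9 adjusted over the list alone (camera adjusted p = 3.4e-07, adjusted p = 0.111 with an estimated correlation). Of 10 keratin and epithelial genes 2 fell over all genes, the tight junction gene Cldn4 (-2.69) and Krt18 (-1.24), and 5 adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). Of 12 cytotoxic lymphocyte genes 0 passed over all genes and 7 fell adjusted over the list alone, with a median of -1.39 (adjusted p = 0.371 with an estimated correlation), and the macrophage list had a median of -1.36 with 0 of 13 under either (adjusted p = 0.371 with an estimated correlation). The growth factor gene Bmp7, the glycine transporter gene Slc6a9, the centromere gene Cenpv and the protease gene Pcsk6 rose by 1.80, 1.66, 1.65 and 1.46, and the serine and asparagine synthesis genes Psat1 and Asns by 0.92 and 0.72.

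In all, 152 of 13840 genes changed under isotype antibody, 60 higher and 92 lower, and quantile scaling gave 80 higher and 69 lower. With only the 6 libraries compared in the model 52 passed, with no filter 89 and by voom 50. Leaving out WGD- replicate 1, 2 or 3 gave 41, 43 or 20 genes and leaving out WGD+ replicate 1, 2 or 3 gave 56, 66 or 85. The library labelled WGD+ replicate 2 had a genotype score of -0.157, the lowest of the 9 WGD+ libraries of this table. By the level of genes on chromosomes 2, 5 and 14, taken up further below, it lay at 0.124. The WGD- libraries of this table lay between 0.0469 and 0.0858 on that measure, so its genotype is in doubt. The skeletal muscle list ranged from 2.46 to 8.27 over the WGD- isotype libraries. Of the 18 named genes past the threshold, 5 stayed past it with each library left out: Cenpv, Cldn4, Pcsk6, Psat1 and Ptgs2.

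Anti-PD-L1 was compared with isotype in each form. Cd274, the gene of its target (chromosome 19, 29367455 to 29388095), was at 5.52 ± 1.33 against 5.20 ± 0.48 in WGD- tumours (SD, n = 3 each) and at 4.65 ± 1.39 against 3.32 ± 1.08 in WGD+ tumours, and passed in neither (0.32 and 1.34, SE 0.73 in each, limma adjusted p = 0.969 and 1). In WGD- tumours 1 gene passed, Apoc1, an apolipoprotein gene (chromosome 7, 19689481 to 19692660), at 0.84 ± 0.22 against 3.04 ± 0.46 (-2.19, SE 0.27, adjusted p = 0.00499). It kept its call with each library left out, at -1.93 without isotype replicate 2 (adjusted p = 0.0439). That library held liver transcripts, with Alb at 8.26 and 26 liver genes at 0.0751% of the CPM, and Apoc1 at 3.56 against 2.75 and 2.79 in the other isotype libraries. Their source in that library was not tested. Without anti-PD-L1 replicate 3, 525 genes passed, and with only the 6 libraries compared in the model, or by voom, 0 did. The macrophage list was called higher in both forms, with a median of 0.94 in WGD- and 1.24 in WGD+ tumours, 0 of 13 genes past the threshold over all genes in either, and 0 and 3 adjusted over the list alone (adjusted p = 0.876 and 0.544 with an estimated correlation). Its mean level was 7.15 against 6.14 in WGD- and 6.05 against 4.84 in WGD+ tumours. The interferon-gamma list was called higher in WGD+ tumours with a median of 1.23 and 0 of 18 genes past either adjustment (camera adjusted p = 1.67e-08, adjusted p = 0.544 with an estimated correlation). In WGD+ tumours limma called 0 of 13840 genes, with 504 at an unadjusted p under 0.05 and 0 by voom. The WGD+ isotype group holds the library labelled replicate 2, whose genotype is in doubt, as 1 of its 3 libraries. With that library left out the count stayed at 0, and the list calls without it are not given here. That library also enters the interaction. The interaction of antibody and form had 0 genes (232 at an unadjusted p under 0.05, voom 0), and its interferon-gamma list had a median of 0.94 (camera adjusted p = 0.00112, adjusted p = 0.896 with an estimated correlation).

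Anti-CD8 was compared with the same isotype libraries. Cd8a (chromosome 6, 71373427 to 71379173), the alpha chain of the target, was at 0.52 ± 0.21 (n = 2) against 2.62 ± 0.94 (n = 3) in WGD- tumours and at 0.41 ± 0.21 against 0.67 ± 0.38 in WGD+ tumours (n = 3 each), and did not pass in either (-2.09, SE 0.86, limma adjusted p = 0.389, and -0.26, SE 0.77, adjusted p = 0.949). Cd8b1, the beta chain gene, was listed at 0 in both WGD- anti-CD8 libraries and averaged 1.79 ± 1.06 under isotype. In WGD- tumours 12 cytotoxic lymphocyte genes had a median of -1.68, with 0 past the threshold over all genes and 11 lower adjusted over the list alone (camera adjusted p = 1.01e-08, adjusted p = 0.403 with an estimated correlation). The interferon-gamma list had a median of -2.24, with 0 of 18 over all genes and 7 lower adjusted over the list alone (adjusted p = 0.403 with an estimated correlation), and its mean level was 3.27 under anti-CD8 against 5.67. Of 15 p53 target genes 6 were higher adjusted over the list alone and 0 over all genes, with Eda2r at 1.59 and Ccng1 at 1.02 (adjusted p = 0.403 with an estimated correlation). The 1 gene past the threshold was Apoc1 (-2.16, SE 0.30, adjusted p = 0.0249), measured against the isotype libraries used for anti-PD-L1, of which replicate 2 held liver transcripts. Leaving out isotype replicate 1 gave 2 genes and leaving out any other library 0. With only the 5 libraries compared in the model 170 genes passed, and with quantile scaling or by voom 0.

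In WGD+ tumours limma called 0 genes under anti-CD8, with 1041 at an unadjusted p under 0.05 and 0 by voom. The library labelled WGD+ isotype replicate 2, whose genotype is in doubt, is again 1 of the 3 controls, here and in the interaction. The macrophage list was called higher with a median of 1.06 and the hypoxia list lower with a median of -0.73, each with 0 genes past either adjustment (adjusted p = 0.645 with an estimated correlation for both). The interaction of anti-CD8 and form also had 0 genes (2304 at an unadjusted p under 0.05, voom 0). Its macrophage list differed by a median of 2.07 with 0 of 13 genes past either adjustment (camera adjusted p = 2.96e-06, adjusted p = 0.541 with an estimated correlation).

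The time course compared the forms at day 8 and day 14. At day 14 genes of T cells and of the interferon-gamma response were lower in WGD+ tumours. Cxcl9 was at 3.16 ± 1.47 against 7.10 ± 1.00 (SD, n = 3 each), a fall of 3.93 (SE 0.65, limma adjusted p = 0.0413), and Gzmb, a granzyme of cytotoxic lymphocytes (chromosome 14, 56258838 to 56262260), fell by 3.63 (SE 0.50, adjusted p = 0.0252). Gbp4, Gbp5 and Ifi47 fell by 3.69, 3.6 and 3.54, and Irg1, an older symbol of Acod1, by 3.49. Of 17 interferon-gamma genes 8 fell over all genes and 17 adjusted over the list alone, with a median of -2.48 (camera adjusted p = 1.24e-20, adjusted p = 0.265 with an estimated correlation). Of 11 cytotoxic genes 3 fell over all genes (Gzmb, Cd8a -3.33, Nkg7 -2.94) and 10 adjusted over the list alone, and of 12 T cell genes 2 fell over all genes (Cd3g -3.25, Zap70 -2.58) and 10 adjusted over the list alone (adjusted p = 0.265 with an estimated correlation for both lists). The exhaustion marker Pdcd1 fell by 2.94. The cold-inducible RNA-binding protein gene Cirbp and the cytochrome gene Cyp1b1 rose by 1.63 and 1.31. In all, 60 of 13478 genes changed, 6 higher and 54 lower. With only the 6 libraries compared in the model 139 passed, with no filter 15 and by voom 2. Leaving out WGD- replicate 1, 2 or 3 gave 0, 1 or 345 genes and leaving out WGD+ replicate 1, 2 or 3 gave 19, 0 or 2, so that none of the 20 named calls held with each library left out.

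At day 8 the libraries labelled WGD+ were higher in interferon genes. Ifi44 was at 5.79 ± 0.76 against 3.22 ± 0.55 (SD, n = 3 each), a rise of 2.58 (SE 0.38, limma adjusted p = 0.0196), and Gbp5 (chromosome 3, 142493978 to 142522344) rose by 2.34. Of 20 type I interferon genes 2 rose over all genes (Ifi44 and Ifit2, 1.65) and 13 adjusted over the list alone, and of 17 interferon-gamma genes 3 rose over all genes and 10 adjusted over the list alone (adjusted p = 0.572 with an estimated correlation for both). Hypoxia genes were lower, 3 of 12 over all genes and 10 adjusted over the list alone: the angiogenic factor gene Vegfa (chromosome 17, 46016993 to 46032369) fell by 2.44, the carbonic anhydrase gene Car9 by 2.13 and the glucose transporter gene Slc2a1 by 2.0 (adjusted p = 0.572 with an estimated correlation). The stress genes Hspa5, Ddit3 and Trib3 fell by 1.34, 1.05 and 1.04. The urea transporter gene Slc14a1 fell by 3.14 and the ferritin receptor gene Scara5 (chromosome 14, 65666403 to 65764826) by 2.38. In all, 457 of 13478 genes changed, 64 higher and 393 lower, and 50 with no filter or 188 by voom.

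Several day 8 libraries stood apart from their labels. The library labelled WGD- replicate 3 had a genotype score of 0.635 and that labelled WGD+ replicate 3 one of -0.281, against medians of -0.649 for WGD- and 0.608 for WGD+ in this table. The skeletal muscle list ranged from 3.14 to 11.2 over the libraries labelled WGD+ at day 8. The day 8 count was 117, 60 or 246 without the library labelled WGD- replicate 1, 2 or 3, 10 or 0 without that labelled WGD+ replicate 1 or 3, and 1 without WGD- replicate 1 and WGD+ replicate 3, which correlated least with the others. It was 77 when the libraries labelled replicate 3 were left out as well, which leaves 1 WGD- library against 2 with its spread taken from the other groups, and 0 when the model held only the 6 libraries compared. None of the 23 named calls at day 8 held with each library left out.

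**Figure D3:**
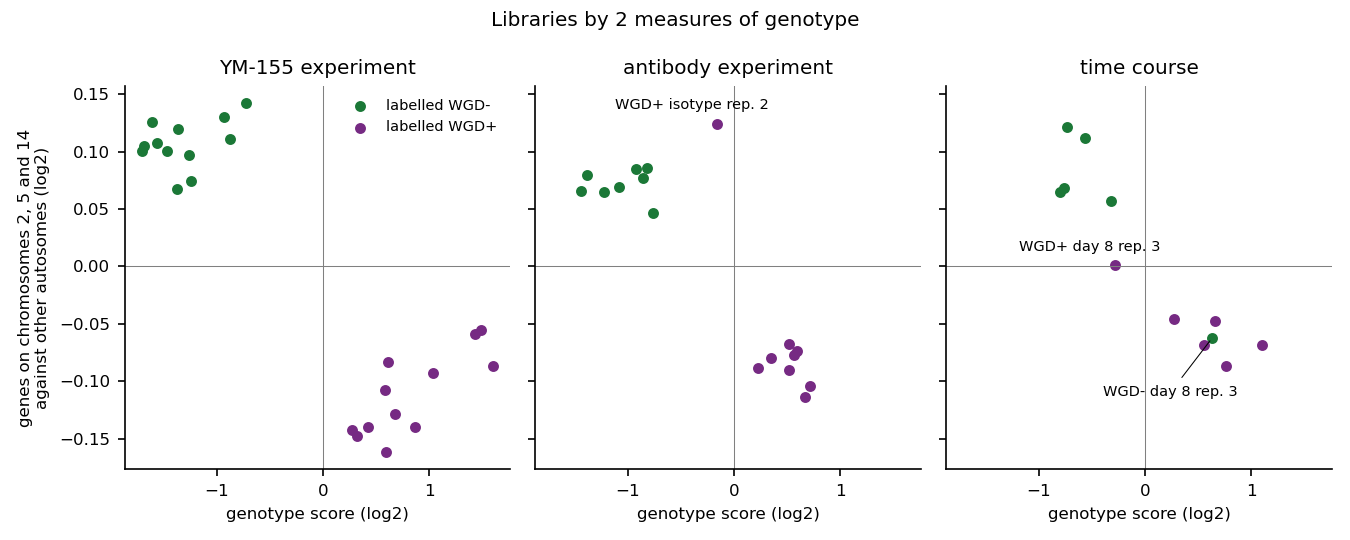
Each library by its genotype score on the horizontal axis and by the level of genes on chromosomes 2, 5 and 14 against the other autosomes on the vertical axis, both in log2 units, in the 3 experiments, coloured by labelled genotype. The library labelled WGD- day 8 replicate 3 lies at 0.635 and -0.062, among libraries labelled WGD+, and that labelled WGD+ isotype replicate 2 lies at -0.157 and 0.124.

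Day 14 was then compared with day 8 within each form. In WGD- tumours genes of activated T cells and of interferon-gamma rose with time: Cxcl9 by 5.01 (SE 0.65, limma adjusted p = 0.00736) to 7.10 ± 1.00 from 2.09 ± 0.39 (SD, n = 3 each), Gbp4 by 4.88, Gbp10 by 4.48, Gbp5 by 4.43 and Gzmb by 4.25. Of 17 interferon-gamma genes 12 rose over all genes and 16 adjusted over the list alone, with a median of 3.37 (camera adjusted p = 5.08e-34, adjusted p = 0.0953 with an estimated correlation). Of 11 cytotoxic genes 5 rose over all genes and 9 adjusted over the list alone, with Cd8a at 4.11, and of 12 T cell genes 4 and 11, with Cd3g at 3.67 (adjusted p = 0.0953 with an estimated correlation for both). Pdcd1, Lag3 and Tigit, inhibitory receptors of T cells, rose by 3.43, 2.47 and 2.35. The genes that fell were Trabd2b (-1.11), Gpt2 (-0.89) and the deacetylase gene Hdac7 (-0.88). In all, 114 genes changed, 111 higher and 3 lower. With only the 6 libraries compared in the model 52 passed, with no filter 64 and by voom 45. The count was 14 or 70 without day 8 replicate 2 or the library labelled replicate 3, and 16, 31 or 228 without day 14 replicate 1, 2 or 3. Gbp10, Gbp4, Gbp5, Gzmb and Ifi44 were the 5 of 30 named genes that stayed past the threshold with each library left out.

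In WGD+ tumours the genes that rose from day 8 to day 14 included Wif1, a secreted inhibitor of Wnt signalling, by 3.6 (SE 0.53, limma adjusted p = 0.014), to 4.08 ± 0.48 from 0.48 ± 0.48 (SD, n = 3 each). Tex101 and the peptidoglycan-binding gene Pglyrp1 rose by 2.92 and 2.75. Hypoxia genes rose, 4 of 12 over all genes and 9 adjusted over the list alone, with Car9 at 2.37, Vegfa at 1.85 and Slc2a1 at 1.82 (camera adjusted p = 0.000138, adjusted p = 0.822 with an estimated correlation). The epithelial genes Cdh1 and Epcam rose by 1.65 and 1.64. Arg1, the arginase of alternatively activated macrophages, fell by 3.35 (SE 0.92, adjusted p = 0.0421), the transcription factor gene Maf by 3.18 and Npl by 3.94. Of 20 type I interferon genes 4 fell under both adjustments, among them Cmpk2 (-2.21) and Ifi44 (-1.88) (adjusted p = 0.822 with an estimated correlation). In all, 1514 genes changed, 944 higher and 570 lower. With no filter 1006 passed and by voom 908. The count was 220 or 273 without day 8 replicate 1 or the library labelled replicate 3, and 282, 317 or 0 without day 14 replicate 1, 2 or 3, and none of the 28 named calls held with each library left out.

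**Figure D4:**
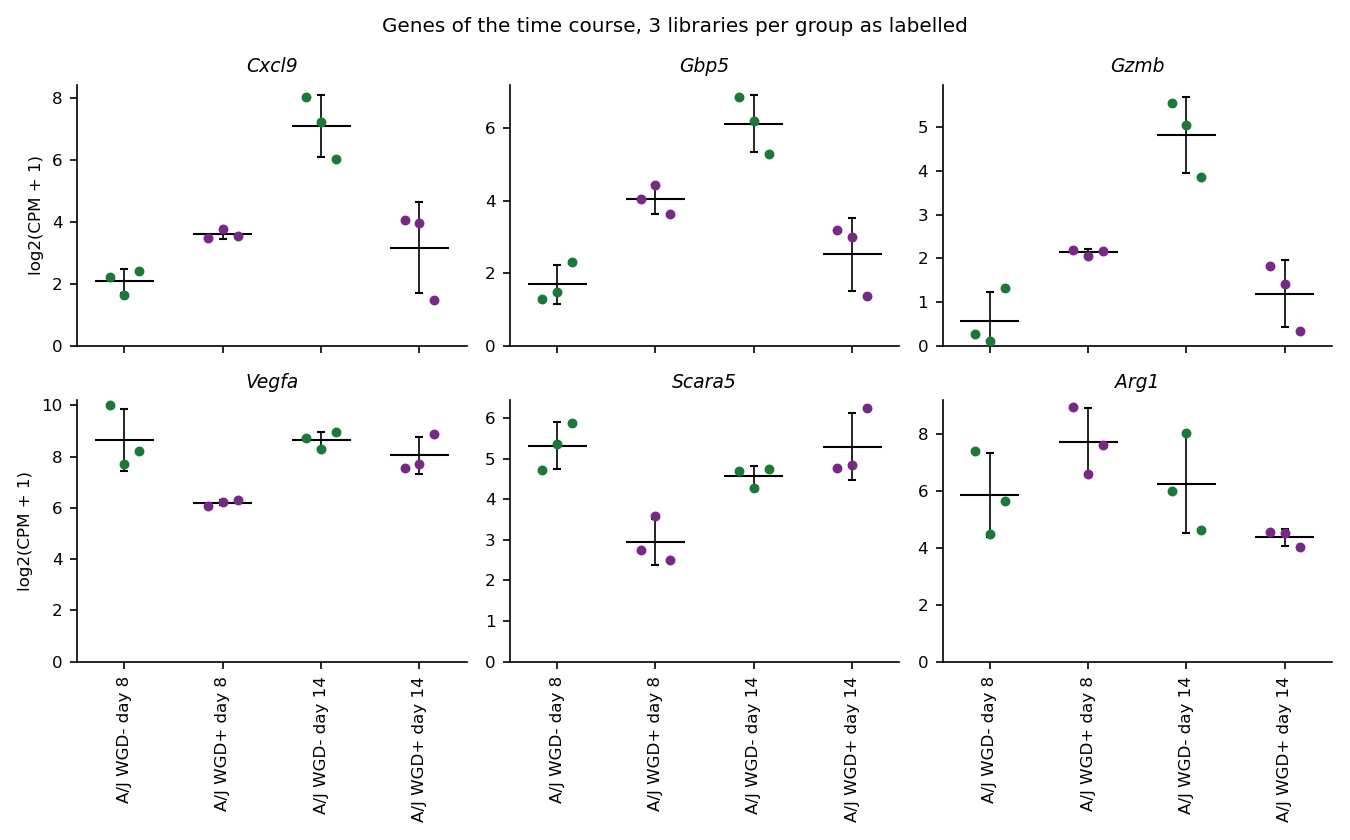
Level of 6 genes, as log2(CPM + 1), in each library of the time course as labelled, with group mean and SD as black lines, WGD- in green and WGD+ in purple. Cxcl9 averaged 2.09 at day 8 and 7.10 at day 14 in WGD- tumours, and 3.16 at day 14 in WGD+ tumours.

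The change from day 8 to day 14 differed between the forms in a test of the interaction. Gbp5 had a difference of -5.94 (SE 0.72, limma adjusted p = 0.00745), with means of 1.69 and 6.12 at day 8 and day 14 in WGD- tumours and 4.03 and 2.52 in WGD+ tumours (n = 3 each). The pattern recognition receptor gene Clec7a, Gbp2b and Ifi47 differed by -5.62, -5.54 and -5.52. Of 17 interferon-gamma genes 13 differed over all genes and 16 adjusted over the list alone, all lower, with a median of -3.92 (camera adjusted p = 3.67e-18, adjusted p = 0.317 with an estimated correlation). Of 20 type I interferon genes 9 and 20 did, led by Ifi44 (-4.80), and of 11 cytotoxic genes 4 and 9, led by Gzmb (-5.20) (adjusted p = 0.317 with an estimated correlation for both lists). In the other direction Scara5, Ggt7, Esyt3 and Papln differed by 3.10, 3.10, 3.09 and 2.79. In all, 461 of 13478 genes differed, 214 higher and 247 lower. With no filter 235 differed and by voom 289. The count was 797 or 187 without day 8 WGD- replicate 1 or the library labelled replicate 3, 146, 28 or 795 without day 14 WGD- replicate 1, 2 or 3, 110, 712 or 189 without the day 8 library labelled WGD+ replicate 1, 2 or 3, and 229, 129 or 98 without day 14 WGD+ replicate 1, 2 or 3. It was 148 without the libraries that stood apart or scored as the other genotype, which leaves 1 WGD- library at day 8 with its spread taken from the other groups. Gbp5, Gzmb, Ifi44, Ifi47 and Oas3 were the 5 of 33 named genes that stayed past the threshold with each library left out.

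The WGD+ and WGD- comparison was made in 3 separate sets of A/J tumours: under vehicle, under isotype antibody and at day 14 of the time course. Vehicle and isotype antibody were given for 14 days and their day of collection is not stated, so tumour age may differ between the sets. Nos2 was lower in WGD+ tumours in all of them (-2.45, -2.99 and -2.86), as were Il24, a cytokine of the interleukin 10 family (-1.76, -2.77 and -2.30), and Gpr137b, a gene of a lysosomal membrane protein (-0.94, -1.68 and -1.03). These 3 genes are the whole overlap of the limma calls among 12846 gene symbols tested in all sets. Independent lists would share 0.018. Genes were matched by symbol, so a gene that the tables carry under different symbols is missed. Acod1, called lower under isotype, and its older symbol Irg1, called lower at day 14, were not matched to each other. Leaving out 1 library at a time gave 0 to 6 shared genes, and no filter or voom 0. Vehicle and isotype shared 23 genes higher and 38 lower, against 3.94 and 4.16 for independent lists. Of the 149 isotype calls tested in the other sets, 143 had the same direction under vehicle and 146 at day 14, and all 58 day 14 calls tested under isotype had the same direction there. Of the vehicle calls, 1370 of 1472 had the same direction under isotype and 1169 of 1486 at day 14. Il24 and Gpr137b fall outside the rule for named genes and were chosen after their values were seen.

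**Figure D5:**
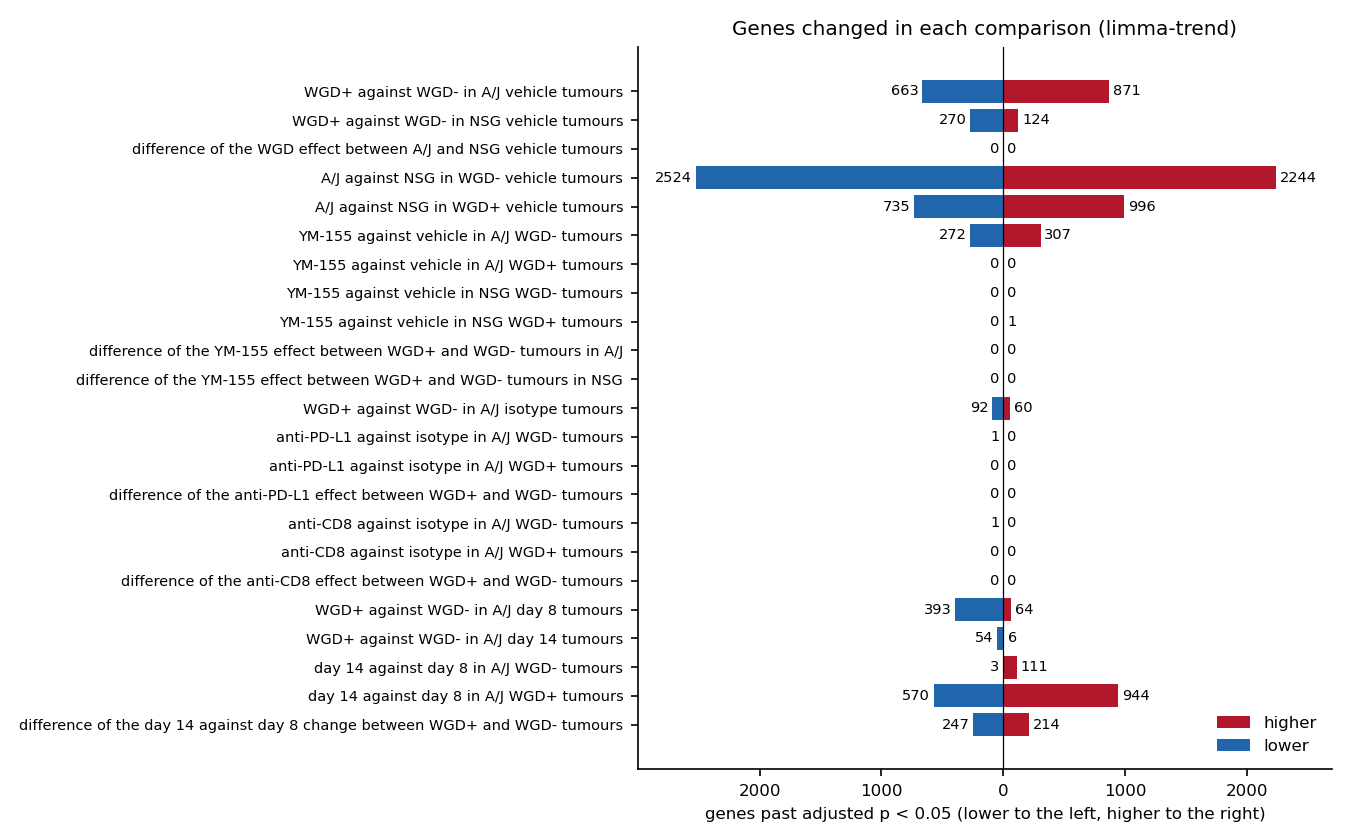
Number of genes past limma adjusted p of 0.05 in each of the 23 comparisons, higher to the right and lower to the left. The longest bars are those of A/J against NSG in WGD- vehicle tumours, with 2244 higher and 2524 lower.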

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

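The tests of muscle RNA, of Alb expression by WGD- tumour cells and of vehicle replicate 2, with its fold changes, were chosen after the results they weigh were seen.

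The response over time differed between the groups as labelled. Of the 6 day 8 libraries, 2 score as the other genotype, as weighed below, and the test takes all labels as given. In a test of the difference itself, the change from day 8 to day 14 differed in 461 genes. Gbp5 (-5.94), Clec7a (-5.62), Gbp2b (-5.54) and Ifi47 (-5.52), genes of the interferon response and of pattern recognition, had the more negative change in WGD+ tumours. Scara5 (3.10), Ggt7 (3.10), Esyt3 (3.09) and Papln (2.79) had the more positive one. In 1 of 100 regroupings of the 12 libraries, the real one, the count was as large, and the highest of the others was 454. This does not exclude chance. The regroupings mix groups that differ by form and day, so they do not show what libraries with an equal response would give. The margin over the highest other is small, and the count moves between 28 and 797 when 1 library is left out. It is lowest without day 14 WGD- replicate 2 and highest without day 8 WGD- replicate 1.

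The first pattern weighed is that 2 day 8 libraries labelled replicate 3 score as the other genotype. In genes outside the score, 45 genes that also changed with genotype elsewhere, the library labelled WGD- replicate 3 lies at 0.971 on a scale where 0 is the WGD- median and 1 the WGD+ median, and WGD- replicate 2 lies at 0.593. A wrong label on that library is a candidate explanation. On chromosomes 2, 5 and 14 it also lies with WGD+ libraries (-0.062). A swap of the 2 labels would need both libraries out of place. That was so for 2 of 2 libraries in genes outside the score. On the chromosomes it was so for 1 of 2, by medians of 0.0666 for WGD- and -0.0580 for WGD+. Those medians included both libraries, whereas the medians for genes outside the score left both out. The library labelled WGD+ replicate 3 stands almost midway at 0.000806. Medians without both libraries would place it marginally nearer WGD-. The chromosomes thus do not decide, and a swap and a single wrong label cannot be told apart. Exchanging the 2 labels is 1 of the splits counted below, so it gives at most 2 genes at day 8 in place of 457. That count does not settle the labels, since it was also 0 without the library labelled WGD+ replicate 3. That library holds much muscle RNA, with Acta1 at 12.1, and whether muscle RNA moves its score stays open: the genes of the score that muscle does not raise differ from the other 2 WGD+ libraries by a median of 0.11 (SE over 81 genes 0.092). No biological explanation was tested. Without the libraries that stand apart or score as the other genotype, 77 genes changed at day 8 in place of 457, but that setting leaves 1 WGD- library, replicate 2, against 2 and takes its spread from the other groups, so it does not settle the labels.

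The second pattern is that liver transcripts lead the falls in A/J WGD+ vehicle tumours. RNA from liver in some A/J WGD- libraries may be the source: of 18 liver genes not looked at before, 18 were higher in the library with most Alb than in every A/J WGD+ vehicle library. In that library, WGD- vehicle replicate 2, Alb was at 10.04 and 26 liver genes held 0.245% of the CPM. The library was chosen by its Alb, and the liver genes seen before were already higher in it. The outcome for the 18 genes was thus likely from the start. Alb was also at 3.86 in NSG WGD+ YM-155 replicate 3 and at 3.10 in A/J WGD+ YM-155 replicate 3. A/J WGD- vehicle replicate 1 held it at 3.48. Expression by WGD- tumour cells as such is argued against, because the highest value of Alb in the NSG WGD- vehicle libraries was 0. Whether the liver RNA came from metastases, from tissue taken with the tumour or from another sample was not tested.

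The third pattern is the set of 579 genes changed under YM-155 in A/J WGD- tumours, a count that no other YM-155 arm approached. Whether they rest on vehicle replicate 2 standing apart stays open. Without that library 0 genes passed, but 0 also passed without YM-155 replicate 3, so a count of 0 does not single it out. All 579 genes kept their direction without vehicle replicate 2, at a median of 0.822 of their fold change with a standard error 1.06 times as large, and without YM-155 replicate 3, at 0.928 and 1.13. A wider error alone does not account for the loss of calls: without vehicle replicate 1 it was 1.13 times as large and 577 genes passed. Without YM-155 replicate 2 it was also 1.13 times as large and 738 passed. The median fold change fell only in the leave-outs with 0 calls. The 579 genes were chosen by their calls, so their kept direction says little. What ended the calls was not tested. Unequal depth is not settled: with all libraries thinned to 3.23 M reads the median count was 369. A change in the macrophage share of the tumour also stays open. The macrophage list moved by a median of -0.887 (SE over genes 0.128) and the 272 falls by -1.40 (SE over genes 0.0404). The bound written beforehand set these against each other, which was wrong, since the falls were chosen by their size. An effect of YM-155 on the A/J WGD- tumours stays among the open explanations.

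Other splits of the same libraries were counted for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so only the real count and the highest other are given. Each other split mixes libraries of the 2 groups compared, so its count does not show what libraries without a difference would give. A low highest other thus does not exclude chance. In 1 split, the real one, the count was as large for WGD in A/J vehicle tumours (1534, highest other 1), in NSG vehicle tumours (394, 0), under isotype (152, 0), at day 8 (457, 2) and at day 14 (60, 0). The same held for hosts in WGD- (4768, 12) and WGD+ tumours (1731, 0), YM-155 in A/J WGD- (579, 41) and NSG WGD+ tumours (1, 0), and time in WGD+ tumours (1514, 0). For time in WGD- tumours 2 splits gave as many (114, highest other 205), and for anti-PD-L1 in WGD- tumours 3 did (1, highest other 1597), so these real counts were not the largest. What sets the other splits apart was not tested. Where limma called 0 genes, all 10 splits must give as many, so the count tests nothing: YM-155 in A/J WGD+ (highest other 4) and NSG WGD- tumours (0), and anti-PD-L1 (0) and anti-CD8 (16) in WGD+ tumours. For the differences between effects with 0 genes, all 100 regroupings must likewise give as many, which tests nothing. Their highest others were 2899 for WGD between hosts, 2466 and 729 for YM-155 in A/J and NSG tumours and 833 for anti-PD-L1, from regroupings that mix groups that differ. The counts of these differences at an unadjusted p under 0.05 were 1787, 1650, 1400 and 232, and voom called 0 in each. Anti-CD8 in WGD- tumours has 2 libraries, so neither it nor its difference was split.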

How the results depend on the processing

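Chosen after the results were seen were the filter on values above 0, voom, and the 2 settings that leave out libraries that stand apart or score as the other genotype; the cause of each change was not tested.

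Counts of genes changed that moved by more than 1.5 times are given by setting. With no filter: WGD in A/J vehicle 908, NSG vehicle 256, isotype 89, day 8 50 and day 14 15; hosts in WGD+ 929; YM-155 in A/J WGD- 69, A/J WGD+ 1 and NSG WGD+ 0; anti-PD-L1 in WGD- 2; time in WGD- 64, WGD+ 1006 and their difference 235; genes shared by the 3 A/J sets 0. With only the libraries of the groups compared: WGD in A/J vehicle 44, NSG vehicle 2462, their difference 2, isotype 52, day 8 0 and day 14 139; hosts in WGD- 2976 and WGD+ 4139; YM-155 in A/J WGD- 1, NSG WGD- 5, NSG WGD+ 0 and the NSG difference 29; anti-PD-L1 in WGD- 0; anti-CD8 in WGD- 170; time in WGD- 52. With quantile normalization: anti-CD8 in WGD- 0, and Rpl3 between hosts in WGD- tumours -0.0051. With log2(2^value + 1) no count moved so far. With values above 0 in 3 libraries: YM-155 in NSG WGD+ 0, day 8 290, day 14 17, shared genes 1. With voom: WGD in A/J vehicle 917, isotype 50, day 8 188 and day 14 2; YM-155 in A/J WGD- 27 and NSG WGD+ 0; anti-PD-L1 and anti-CD8 in WGD- 0 and 0; time in WGD- 45, WGD+ 908 and their difference 289; shared genes 0. Without the libraries that stand apart, which leaves 1 A/J WGD- vehicle library: WGD in A/J vehicle 95 and day 8 1; hosts in WGD- 2310; YM-155 in A/J WGD- 0, with Lum 0.38 and Dcn 0.96; time in WGD+ 911; shared genes 1. Without those or the libraries that score as the other genotype, which leaves 1 WGD- library at day 8: day 8 77, time in WGD- 259, difference 148. Of 263 list calls, 0 were left with camera at an estimated correlation and 76 with fry.

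With the replicate block, a pairing by number that the labels do not state: YM-155 in A/J WGD- 891, isotype 63, day 8 22, day 14 35, time in WGD+ 948, the time difference 231 and shared genes 0.

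Leaving out 1 library at a time gave these lowest and highest counts: WGD in A/J vehicle 445 and 2444, NSG vehicle 107 and 194, their difference 0 and 135, isotype 20 and 85, day 8 0 and 680, day 14 0 and 345; hosts in WGD- 3365 and 4661, in WGD+ 417 and 1374; YM-155 in A/J WGD- 0 and 1815, A/J WGD+ 0 and 12, NSG WGD- 0 and 0, NSG WGD+ 0 and 14, the A/J difference 0 and 199, the NSG difference 0 and 2; anti-PD-L1 in WGD- 1 and 525; anti-CD8 in WGD- 0 and 2; time in WGD- 14 and 228, WGD+ 0 and 1458, difference 28 and 797; lists 245 and 274; shared genes 0 and 6. Anti-PD-L1 and anti-CD8 in WGD+ tumours and the differences of both stayed at 0. With 1 anti-CD8 library left in WGD- tumours, it is assumed to vary like the other groups, as are the lone libraries above. Genes not called whose sign turned have these lowest and highest values: Birc5 -0.12 and 0.17 in A/J WGD-, -0.16 and 0.24 in A/J WGD+, -0.023 and 0.15 in NSG WGD-, -0.14 and 0.26 in the A/J difference; Cidec -2.05 and 0.18 under isotype; in WGD- anti-PD-L1 tumours Adipoq -1.87 and 0.048 and Cd274 -0.20 and 1.07; Cd74 -0.17 and 1.78 in WGD+ anti-PD-L1; Cd8b1 -0.39 and 0.014 in WGD+ anti-CD8.

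Of the 332 named values past the threshold, 190 stayed past it with no filter, 318 with log2(2^value + 1), 310 with quantile normalization, 200 with only the libraries compared, 273 with the replicate block, 278 with values above 0 and 189 with voom. Of 234 such values in the comparisons that hold libraries that stand apart, 111 stayed past it without them, and of 114 with those that score as the other genotype left out too, 43 did. The rest kept their direction and lost the call, except Rpl3. Leaving out 1 library gave 2189 such values, of which 1274 stayed past the threshold and 915 did not.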

Other observations

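The tests here that were chosen after the data were seen are the pooled genotype comparison of the antibody experiment and the choice of chromosomes 2, 5 and 14.

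With the isotype, anti-PD-L1 and anti-CD8 arms of the antibody experiment pooled, 2060 of 13840 genes differed between WGD+ and WGD- tumours, 1088 higher and 972 lower. Under isotype antibody alone 152 did. The pooled comparison sets 9 libraries against 8 and the isotype one 3 against 3, so the 2 counts differ in power. The pooled count holds the library labelled WGD+ isotype replicate 2 and is given under 1 setting only.

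Genes on chromosomes 2, 5 and 14 had median changes below 0 in WGD+ tumours. Their median changes were -0.166, -0.134 and -0.165 in NSG vehicle tumours, -0.206, -0.204 and -0.183 in A/J vehicle tumours, -0.0926, -0.0296 and -0.104 under isotype and -0.149, -0.0995 and -0.101 at day 14. Under isotype chromosome 5 does not stand out: its median lies at -1.91 SD of random gene sets, and chromosome 19 is lower there, at -0.0438. A candidate explanation is a copy-number difference between the WGD+ and WGD- lines, which would shift the same chromosomes in separate tumours. Over 20 chromosomes the medians of NSG vehicle and A/J isotype tumours correlated with a Pearson r of 0.651 (permutation p = 0.00197, adjusted p = 0.00236 over 6 pairs of comparisons). The Spearman correlation was 0.379 (p = 0.0991), and without the 2 farthest chromosomes r was 0.251, so for this pair the relation rests on few chromosomes. Among the A/J sets it held more widely: vehicle with isotype had a Spearman correlation of 0.608 (adjusted p = 0.0107) and r of 0.757 without the 2 farthest, vehicle with day 14 had 0.669 (adjusted p = 0.00588) and 0.693, and isotype with day 14 had 0.660 (adjusted p = 0.00588) and 0.541. NSG vehicle with A/J vehicle had 0.393 (adjusted p = 0.119) and 0.551, and NSG vehicle with day 14 had 0.104 (adjusted p = 0.663) and 0.0713. The A/J sets share a host, so their closer correlation with one another does not single out copy number. The shift ran along the chromosomes, with 12 of 12 parts below 0 in NSG vehicle tumours, though the chromosomes were chosen on those same libraries and the first part of chromosome 2 was at only -0.0075. The expression level of these genes is argued against as the whole cause in NSG vehicle tumours. The median over their 2327 genes was -0.1558 (SE over genes 0.0102) after a trend on level was removed and -0.155 before. That SE treats genes as independent and does not measure the spread between tumours. DNA was not measured in these data, so copy number itself was not tested.

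By the level of these chromosomes, 24 of 24 libraries of the YM-155 experiment, 16 of 17 of the antibody experiment and 11 of 12 of the time course lie nearer their labelled genotype. The medians used included every library of a table. The library labelled WGD+ day 8 replicate 3 lies almost midway, and its place among the 11 depends on that choice. The 6 NSG vehicle libraries among the 24 chose the chromosomes and so are no test. The exception in the antibody experiment is the library labelled WGD+ isotype replicate 2, at 0.124 where WGD- libraries lie between 0.0469 and 0.0858. Its genotype score is -0.157, between the forms. Without it 66 genes changed under isotype in place of 152. A mixed or mislabelled sample was not tested for that library.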
